A study of Homo sapiens with 8 samples.

How the data were processed

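RNA sequencing was done on 8 samples in 4 groups. MCF10A cells, a non-tumorigenic human mammary epithelial line, and a derivative that the labels describe as MCF10A with the intracellular domain of NOTCH1 overexpressed were each treated for 3 days with 30 µM ginkgolic acid, an inhibitor of SUMO conjugation, or with its solvent DMSO. Each group had 2 samples. The labels do not say whether these came from separate cultures. Total RNA was isolated with RNeasy columns and made into libraries with the ScriptSeq Complete Gold kit, per the labels' protocols.

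Reads were processed with TopHat2 2.0.8b, Bowtie2 2.1.0, Cufflinks 2.1.1 and Cuffdiff 2.1.1 on the human build GRCh37 (hg19), per the submitters' processing notes. The annotation, the settings and the way in which the 2 samples of a group were combined are not given in the sources used here. The authors deposited 2 tables, 1 for each line, and per the file headers their values are FPKM, fragments scaled by transcript length and by the number of mapped fragments. Each table gives 1 FPKM value per gene and group, so the spread between samples cannot be computed from it. The depth of the libraries is unknown, and no interval or limit that needs it is given. FPKM values of short genes and of genes that hold small RNAs in their introns depend on few fragments or on reads of the small RNA, and the tables do not separate these. Each table was normalized separately, so comparisons were made within a table, and levels set side by side across the tables carry an unknown factor between them.

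The table for MCF10A had 70227 rows, of which 15977 named no gene and 1575 joined several genes. The table for the NOTCH1 line had 59662 rows, of which 5455 named no gene and 1570 joined several genes. Unnamed and joined rows, small RNAs under 200 bases, rows outside the main chromosomes and symbols listed more than 1 time were left out, which left 43063 and 43098 gene rows. A gene counted as measured with at least 1 FPKM in either group of a table. Ratios were log2 of ginkgolic acid over DMSO without a pseudocount, and genes listed at 0 in a group were counted without a ratio, since a listed 0 can be a failed estimate. Gene positions are those of the tables, on hg19. GENCODE release 29 served for gene types, gene lengths and the small RNAs that a gene holds, and not for positions.

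The planned threshold was a q-value in the authors' tables or, with values per sample, a fitted test. The tables used here hold neither, so no test was run, and a size rule of at least 2-fold (an absolute log2 ratio of at least 1) took its place. "Higher" and "lower" refer to the values of the groups and carry no statement on replicate error. For the difference of the responses between lines, the log2 ratio in MCF10A was subtracted from that in the NOTCH1 line. Overlaps are given beside n1 × n2 / N, the number if the 2 sets were independent, and the 2 comparisons share no libraries. Correlations are across genes, which are not independent replicates, and have no p-value.

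The 36 gene lists were fixed before the data were examined, 4 of them with markers of other cell types. The median log2 ratio of each list was placed among 10000 random lists of the same size matched on mean expression in 10 bins. The resulting percentile describes these libraries and is no test. In 100 simulated lists of 20 genes, 4% of lists without a shift lay outside the 95% range in MCF10A and 5% in the NOTCH1 line. With a shift of 0.5 on the log2 scale, 33% and 48% lay outside it, and with a shift of 1, 94% and 92%.

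The rule for named genes was also fixed before the data were examined. Per line it took the 10 genes with the highest and the 10 with the lowest ratio among those with at least 1 FPKM in both groups and at least 2-fold apart. It added up to 4 members per list with the largest absolute ratio beyond 2-fold, and up to 3 names for genes at 0 in a group. It also added the 5 largest differences between lines in each direction, among genes with at least 1 FPKM in all 4 groups. NOTCH1, SUMO2, SUMO3, SAE1, UBA2, HES1, HEY1, HEY2, HEYL, NRARP, MYC and CDKN1A were named whatever their values. Some genes that the rule takes are not reported here. Genes named outside this rule were chosen after their values were seen, and this is said where they appear.

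Before the data were examined, these other settings were listed: no minimum FPKM, a minimum of 5 FPKM, a pseudocount of 1 FPKM, means in place of medians, random lists not matched on expression, and removal of the median ratio between or within the tables. Further settings were added after seeing the data: joined loci kept, unnamed loci kept, list medians centred on the median gene, list members on joined loci added, and genes that hold small RNAs left out. Computations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Random draws used fixed seeds.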

Results

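To find out how MCF10A cells with and without NOTCH1 activation respond to inhibition of SUMO conjugation, total RNA was sequenced from both lines after 3 days with 30 µM ginkgolic acid or with DMSO. The 8 samples formed 4 groups of 2. The deposited values were 1 FPKM per gene and group, so no value below has a replicate error, no difference was tested, and the depth of the samples is unknown. In MCF10A, 20210 genes reached 1 FPKM in either group and 13049 in both. In the NOTCH1 line these numbers were 22162 and 14433.

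NOTCH1, the receptor for which the second line is named, was at 5.03 FPKM in the NOTCH1-labelled DMSO group and at 11.4 FPKM in the MCF10A-labelled DMSO group. With ginkgolic acid it was at 12.4 and 6.18 FPKM. The DMSO values go against the label, although the tables were normalized separately. NOTCH1 lies on chromosome 9 from 139388896 to 139440376 (hg19), and its FPKM covers the whole gene and does not separate the intracellular domain. The line is therefore called NOTCH1-labelled throughout, and directions drawn between the lines rest on that label. HES1, a transcriptional repressor and direct Notch target (chromosome 3, 193853934 to 193856521), was at 45.4 FPKM in NOTCH1-labelled and 36.6 FPKM in MCF10A-labelled DMSO cells.

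Among other genes of the 2 DMSO groups, set side by side across separately normalized tables, inflammatory and NF-kB targets were higher in the NOTCH1-labelled group, with a median log2 ratio of 1.02 and 17 of 31 genes at least 2-fold higher. Type I interferon-stimulated genes had a median of 0.49, with 11 of 35 at least 2-fold higher. Replication-dependent histone genes were lower, with a median of −1.12 and 24 of 43 at least 2-fold lower, and genes of G2 phase and mitosis had a median of −0.57, with 15 of 36 at least 2-fold lower. Notch targets, at −0.20, and Notch receptors, ligands and modulators, at −0.29, had medians inside the 95% range of random lists. Over 18100 genes the median was 0.20, and over the 11781 genes with at least 1 FPKM in all 4 groups it was 0.02. Of the 18100 genes, 4694 were at least 2-fold higher and 1839 at least 2-fold lower in the NOTCH1-labelled group.

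In MCF10A, mitotic genes and many targets of ATF4 and CHOP were higher with ginkgolic acid, and keratinocyte differentiation genes were lower. Of 37 measured genes of G2 phase and mitosis, 35 were at least 2-fold higher and 0 were at least 2-fold lower, with a median log2 ratio of 1.84. PLK1, a kinase of mitotic entry (chromosome 16, 23688977 to 23724821), was at 19.2 FPKM with ginkgolic acid and 2.88 with DMSO, and the centromere protein gene CENPF at 46.5 and 7.96. BUB1, of the spindle checkpoint, had a log2 ratio of 2.76. Genes of S phase and DNA replication had a median of −0.14, with 4 of 34 at least 2-fold higher and 5 at least 2-fold lower. Replication-dependent histone genes had a median of 0.43, with 16 of 42 at least 2-fold higher, at a percentile of 100 that was 93.7 against random lists not matched on expression. HIST1H2BJ was at 283 FPKM with ginkgolic acid and 43.3 with DMSO.

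Targets of ATF4 and CHOP, the transcription factors of the integrated stress response, had a median of 0.87 in MCF10A, with 19 of 39 at least 2-fold higher and 3 at least 2-fold lower. DDIT3, which encodes CHOP, was at 86.5 FPKM with ginkgolic acid and 6.85 with DMSO, and PPP1R15A, a regulatory subunit of the phosphatase that acts on eIF2α, at 206 and 15.4. GDF15, a stress-induced cytokine and p53 target (chromosome 19, 18496968 to 18499986), was at 103 and 5.04 FPKM. DDIT3 and GDF15 hold annotated small RNAs. Genes of the unfolded protein response had a median of 0.38, with 6 of 21 at least 2-fold higher, among them HERPUD1 with a log2 ratio of 3.25 and the chaperone gene HSPA5 with 2.20. The percentile of this list was 99.6, with 92.5 without genes that hold small RNAs and 82.5 against random lists not matched on expression.

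Genes of cholesterol synthesis and uptake had a median of 0.58 in MCF10A, with 6 of 22 at least 2-fold higher and 2 at least 2-fold lower. INSIG1, which retains the sterol sensor SCAP in the endoplasmic reticulum (chromosome 7, 155089486 to 155101945), had a log2 ratio of 4.29 and was at 6.13 FPKM with DMSO. HMGCS1 and MSMO1, enzymes of the pathway, had log2 ratios of 2.37 and 2.51. Genes of the NRF2 and oxidative stress response had a median of 0.44, with 6 of 26 at least 2-fold higher. SQSTM1, an autophagy receptor, was at 516 and 115 FPKM, and HMOX1, which degrades heme, at 4.35 and 0.629. Against random lists not matched on expression, the percentile was 94.0 for the cholesterol list and 89.6 for the NRF2 list.

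Keratinocyte differentiation genes had the lowest median of all lists in MCF10A, −2.28, with 17 of 19 at least 2-fold lower and 0 at least 2-fold higher. TGM1, which cross-links the cornified envelope (chromosome 14, 24718320 to 24733638), was at 1.23 FPKM with ginkgolic acid and 42.0 with DMSO. SPRR1B, a cornified envelope precursor, was at 5.82 and 66.4 FPKM, and S100A7 at 0.632 and 13.5. Of 19 basal epithelial markers, 12 were at least 2-fold lower and 2 at least 2-fold higher, with a median of −1.19. The keratin gene KRT15, in the luminal and glandular list (chromosome 17, 39669995 to 39678781), was at 38.2 and 1241 FPKM and holds an annotated small RNA. Also among the 10 lowest were the alarmin gene S100A8, at 9.09 and 355 FPKM, the growth factor receptor gene FGFR3, at 1.23 and 42.8, and the epithelial transcription factor gene EHF, at 2.36 and 105.

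Type I interferon-stimulated genes had a median of −0.65 in MCF10A, with 13 of 33 at least 2-fold lower and 4 at least 2-fold higher. BST2, an antiviral tether, was at 1.28 FPKM with ginkgolic acid and 11.8 with DMSO. MYC targets and genes of ribosome biogenesis had a median of −0.63, with 8 of 31 at least 2-fold lower and 0 at least 2-fold higher, and MYC itself was at 35.2 and 105 FPKM. Ribosomal protein genes, 29 of 65 of which hold annotated small RNAs, had a median of −0.41, at a percentile of 0.17 that was 3.52 without these genes. p53 targets had a median of −0.23, with 5 of 31 at least 2-fold higher and 4 at least 2-fold lower. The cell cycle inhibitor gene CDKN1A was at 77.3 and 34.6 FPKM, and SFN, a p53 target also in the basal list, at 23.4 and 137.

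Notch targets in MCF10A went both ways, with 4 of 14 at least 2-fold higher, 4 at least 2-fold lower and a median of −0.78. With the mean in place of the median the value was −0.11, at a percentile of 28.8. HES1 was at 179 FPKM with ginkgolic acid and 36.6 with DMSO, and HES4 at 5.02 and 18.5. HEY1 was at 2.73 and 0.404 FPKM, HEY2 at 0.483 and 0.0251, HEYL at 0.260 with DMSO listed at 0, and NRARP at 0.548 in both groups. Olfactory receptor genes, which are mostly silent outside sensory neurons and were chosen after seeing the data, had a mean of 0.624 FPKM with ginkgolic acid and 0.258 with DMSO. HEY2, HEYL and NRARP lay below that mean with ginkgolic acid. With DMSO, HEY2 and HEYL lay below it and NRARP above it. Notch receptors, ligands and modulators had a median of −0.79, with 0 of 18 at least 2-fold higher and 3 at least 2-fold lower. The percentile of that list was 0.18, and 3.02 without genes that hold small RNAs.

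Genes of the SUMO machinery, the process that ginkgolic acid inhibits, had a median of −0.10 in MCF10A, at a percentile of 58.0. SAE1 and UBA2, the subunits of the activating enzyme, were at 57.1 FPKM with ginkgolic acid and 57.2 with DMSO and at 71.8 and 59.1. SUMO2 shares its row with HN1, at 312 and 315 FPKM, and SUMO3 its row with 3 other symbols, at 38.3 and 66.0. The sign of this median flips when the median of genes with at least 1 FPKM in both groups is removed.

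In all, 4302 of 17683 MCF10A genes were at least 2-fold higher with ginkgolic acid and 2682 at least 2-fold lower, so 61.6% of genes beyond 2-fold were higher. With a minimum of 5 FPKM the counts were 1166 and 1561, and 42.8% were higher. The median log2 ratio of genes with at least 1 FPKM in both groups was −0.11. A further 2071 genes were at 0 with DMSO and reached 1 FPKM with ginkgolic acid (J01415.5, AC095064.1 and GLUDP5 at the highest level), and 456 were at 0 with ginkgolic acid (AL662890.3, AL117380.2 and AC025674.1). The largest ratio belonged to ADRBK2, at 73356 and 5.81 FPKM, and AKIRIN2 was at 10315 and 270.2.

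In NOTCH1-labelled cells, mitotic genes and many targets of ATF4 and CHOP were also higher with ginkgolic acid. All 37 measured genes of G2 phase and mitosis were at least 2-fold higher, with a median log2 ratio of 3.89. TOP2A, the topoisomerase of chromosome segregation (chromosome 17, 38544737 to 38574202), was at 313 FPKM with ginkgolic acid and 4.95 with DMSO. KIF20A, a kinesin of cytokinesis, was at 109 and 1.21 FPKM, and PLK1 at 64.4 and 1.93. Genes of S phase and DNA replication had a median of 1.14, with 19 of 35 at least 2-fold higher and 2 at least 2-fold lower, and the replication factor gene CDC45 was at 20.8 and 1.38 FPKM. Replication-dependent histone genes had a median of 2.18, with 35 of 43 at least 2-fold higher and 0 at least 2-fold lower.

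Targets of ATF4 and CHOP had a median of 1.44 in NOTCH1-labelled cells, with 25 of 39 at least 2-fold higher and 0 at least 2-fold lower. DDIT3 was at 515 FPKM with ginkgolic acid and 6.82 with DMSO, GDF15 at 292 and 1.82, and TRIB3, a pseudokinase gene of the same response, had a log2 ratio of 4.89. Genes of cholesterol synthesis and uptake had a median of 1.66, with 14 of 22 at least 2-fold higher, and INSIG1 was at 106 and 4.86 FPKM. Genes of the NRF2 and oxidative stress response had a median of 1.24, with 14 of 27 at least 2-fold higher. HMOX1 was at 48.7 and 0.766 FPKM, and FTL, a ferritin subunit gene, at 1151 and 82.5. Genes of the unfolded protein response had a median of 0.82, with 7 of 20 at least 2-fold higher, and HSPA5 was at 253 and 30.7 FPKM.

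Notch targets had a median of 0.96 in NOTCH1-labelled cells, with 7 of 16 at least 2-fold higher and 0 at least 2-fold lower. HES1 was at 508 FPKM with ginkgolic acid and 45.4 with DMSO, and CDKN1A at 121 and 10.4. HEY1 was at 1.22 and 2.02 FPKM, HEY2 at 0.274 and 0.498, HEYL at 0.382 and 0.319, and NRARP at 2.0 and 1.0, where olfactory receptor genes had means of 0.413 and 0.646. p53 targets had a median of 0.66, with 8 of 31 at least 2-fold higher and 1 at least 2-fold lower, and GADD45A, a growth arrest gene, was at 238 and 12.6 FPKM. Notch receptors, ligands and modulators had a median of 0.48, with 4 of 18 at least 2-fold higher and 3 at least 2-fold lower.

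Keratinocyte differentiation genes had a median of 0.35 in NOTCH1-labelled cells, with 8 of 23 at least 2-fold higher and 3 at least 2-fold lower. This median lay inside the range of random lists, at a percentile of 84.1. SPRR1B was at 46.3 FPKM with ginkgolic acid and 35.5 with DMSO, and S100A7 at 241 and 214, whereas TGM1, at 21.4 FPKM with DMSO, had a log2 ratio of −4.09. Basal markers had a median of 0.24, also inside the range at a percentile of 44.4, with 5 of 21 at least 2-fold higher and 1 at least 2-fold lower. KRT15 was at 154 and 3067 FPKM, and FGFR3 at 3.34 and 46.0. MYC targets and genes of ribosome biogenesis had a median of −0.50, with 11 of 31 at least 2-fold lower and 0 at least 2-fold higher, although MYC was at 79.0 and 69.5 FPKM. Of these 31 genes 12 hold annotated small RNAs, among them NOP58, at 117 and 1211 FPKM. Type I interferon-stimulated genes had a median of −0.28, with 5 of 35 at least 2-fold higher and 5 at least 2-fold lower. The percentile of that list was 2.25, and 10.3 with the mean in place of the median.

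SUMO machinery genes had a median of 0.38 in NOTCH1-labelled cells, at a percentile of 75.4. SAE1 was at 64.5 FPKM with ginkgolic acid and 31.9 with DMSO, and UBA2 at 65.8 and 54.4. The joined row of SUMO2 was at 335 and 271 FPKM, and that of SUMO3 at 40.2 and 51.4. Ribosomal protein genes had a median of 0.08, which turns to −0.13 with the mean and is also below 0 when the median of genes with at least 1 FPKM in both groups is removed.

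Of 19559 genes in NOTCH1-labelled cells, 3706 were at least 2-fold higher with ginkgolic acid and 3694 at least 2-fold lower, so 50.1% of genes beyond 2-fold were higher. With a minimum of 5 FPKM the counts were 1941 and 929, and 67.6% were higher. The median log2 ratio of genes with at least 1 FPKM in both groups was 0.14. A further 838 genes were at 0 with DMSO (AC095064.1, CTD-3244O18.7 and IGLJ6 at the highest level) and 1765 at 0 with ginkgolic acid (AC004492.1, AL121932.1 and TRAJ27). The largest ratio belonged to POFUT1, the fucosyltransferase of Notch, at 6365 and 16.8 FPKM in NOTCH1-labelled cells and 11.4 and 28.8 in MCF10A. POFUT1 holds an annotated small RNA.

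**Figure D1:**
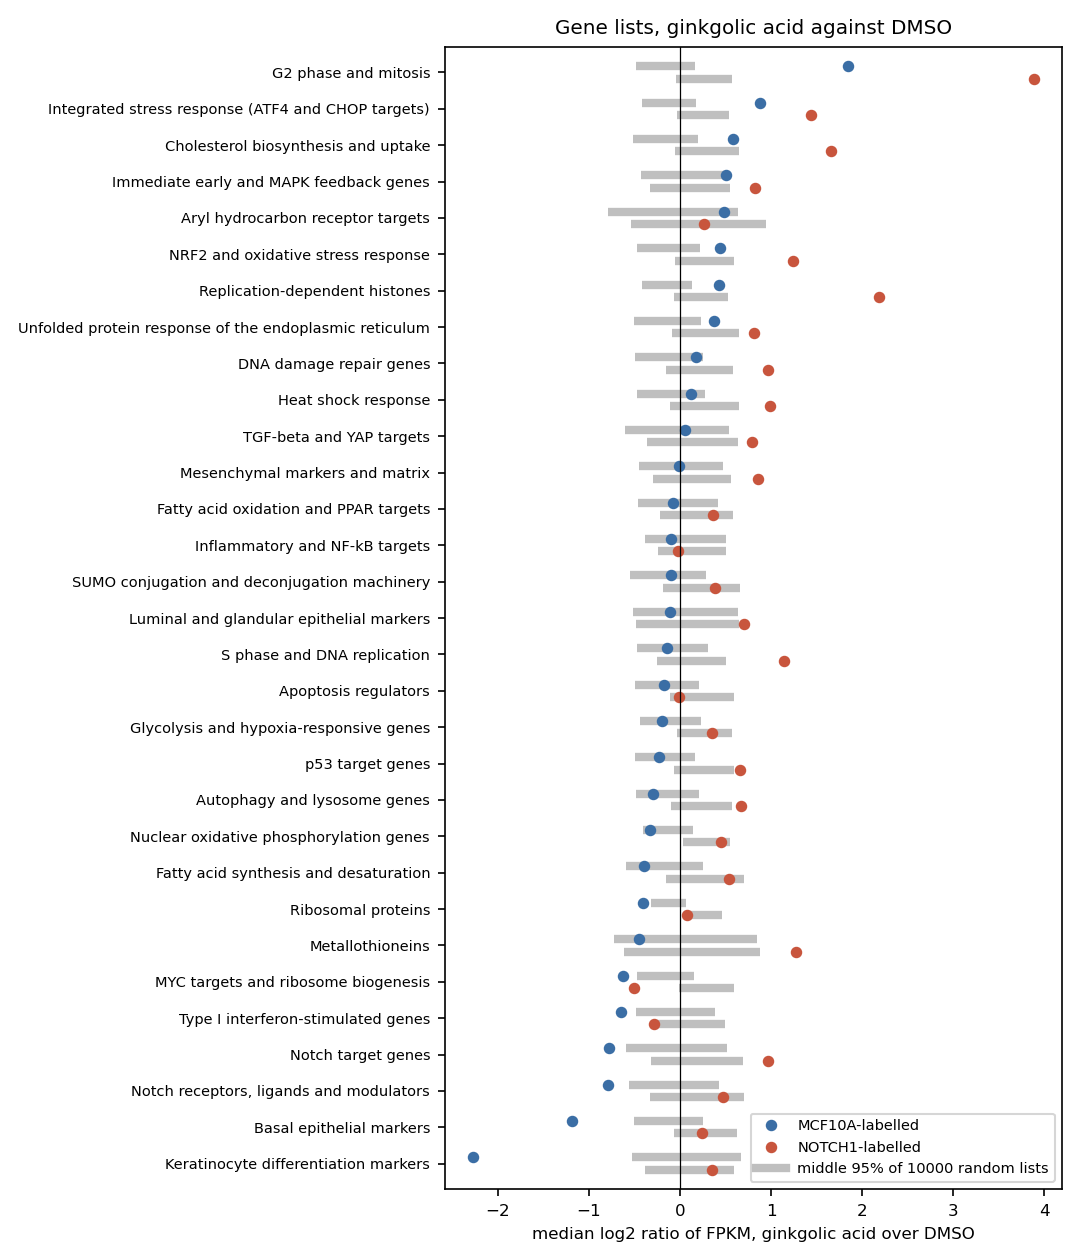
Median log2 ratio of ginkgolic acid over DMSO for gene lists other than markers of other cell types in MCF10A and in NOTCH1-labelled cells, with the 95% range of 10000 random lists matched on expression. The list of G2 phase and mitosis lies at 1.84 and 3.89, and keratinocyte differentiation genes at −2.28 and 0.35.

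**Figure D2:**
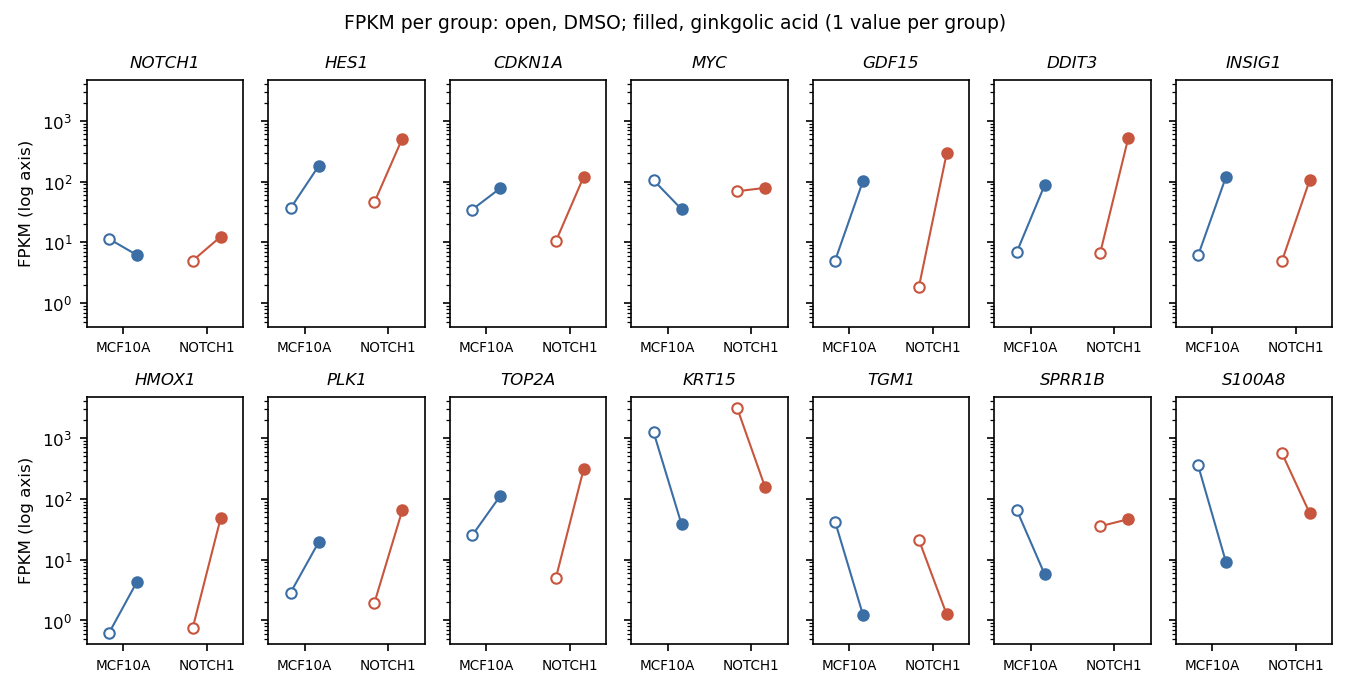
FPKM of 14 genes in the 4 groups on a log axis, 1 value per group and no replicate error, with genes picked for the plot from the named genes after their values were seen. GDF15 is at 5.04 and 103 FPKM in MCF10A and at 1.82 and 292 in NOTCH1-labelled cells with DMSO and ginkgolic acid.

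To ask whether the NOTCH1-labelled line responds differently, the log2 ratios of both lines were compared over 15505 genes. Keratinocyte differentiation genes differed most among the lists, with a median difference of 2.74, and 17 of 18 were at least 2-fold higher in the NOTCH1-labelled response. Genes of G2 phase and mitosis had a median difference of 1.98, with 33 of 37 at least 2-fold higher, and replication-dependent histone genes 1.29, with 28 of 41. Basal markers differed by 1.19, Notch targets by 1.17, p53 targets by 1.07, and genes of S phase and DNA replication by 0.97. All of these lay above the 95% range of random lists. SUMO machinery genes differed by 0.28 and genes of the unfolded protein response by 0.49, inside that range. A lower starting level can also raise such a difference. The DMSO medians, NOTCH1-labelled over MCF10A across separately normalized tables, were −1.12 for histone and −0.57 for mitotic genes. They were −0.46 for basal markers, −0.44 for p53 targets and −0.27 for S phase genes, all below the range of random lists. Those of keratinocyte differentiation genes, −0.25, and Notch targets, −0.20, lay inside it. Whether the lists respond more or start lower was not tested.

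Single genes were ranked among the 11781 with at least 1 FPKM in all 4 groups, which leaves out genes such as CSMD1 at −9.24. The largest differences among them were those of PAQR5, RALGAPA1, ANKRD54, POFUT1 and UBAP2. They were 11.51, 11.50, 11.48, 9.90 and 9.45 in favour of the NOTCH1-labelled response. In the other direction, ADRBK2 had −13.53, SLC9A3R1 −7.64, AL591516.5 −5.75, DGCR8 −5.21 and ANKRD30BL −5.17. PAQR5, ANKRD54, POFUT1, UBAP2, DGCR8 and ANKRD30BL hold annotated small RNAs. For ADRBK2 and AL591516.5 this was not determined, since no entry was found under these symbols in the annotation used. Of the 15505 genes, 3340 had a log2 ratio higher by at least 1 in NOTCH1-labelled cells and 3484 lower by at least 1, with a median difference of 0.22. With a minimum of 5 FPKM these counts were 2174 and 700. The differences were not tested, since no replicate error can be had.

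Some genes lay on the same side in both lines. KRT15, TGM1, FGFR3 and S100A8 were at least 2-fold lower with ginkgolic acid in both lines, and GDF15, DDIT3, INSIG1, HMOX1, PLK1 and HES1 at least 2-fold higher. In total 802 genes were at least 2-fold higher in both, where 556 would be if the sets were independent, and 617 were lower in both, where 331 would be. A further 760 were higher in MCF10A and lower in NOTCH1-labelled cells, where 496 would be, and 184 the other way, where 371 would be. Across genes, which are not independent replicates, Pearson's r was 0.11 and Spearman's rho 0.12. With a minimum of 5 FPKM, r was 0.38, and 425 and 312 genes were higher and lower in both lines, where 179 and 100.2 would be.

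Genes at low level went different ways in the lines. Genes with a geometric mean between 0.1 and 1 FPKM had a median log2 ratio of 0.83 in MCF10A and −0.47 in NOTCH1-labelled cells, and those between 20 and 100 FPKM −0.15 and 0.32. The mean FPKM of olfactory receptor genes was 2.42 times higher with ginkgolic acid in MCF10A (95% bootstrap range over 687 genes 2.19 to 2.68), and in NOTCH1-labelled cells the ratio was 0.639 (0.582 to 0.697 over 688 genes). These ranges cover the choice of genes and not the replicates. Markers of leukocytes had medians of 1.13 and 0.90, of fibroblasts −0.01 and −0.34, of endothelial cells 0.02 and −0.47, and of adipocytes 1.70 and −0.07, all inside the 95% range of random lists. The sign of the fibroblast median in MCF10A flips when the median of genes with at least 1 FPKM in both groups is removed. CD4 and CD3E, T cell markers, were at 1.61 and 2.31 FPKM with ginkgolic acid and 0.105 and 0.224 with DMSO in MCF10A, where olfactory receptor genes had means of 0.624 and 0.258.

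**Figure D3:**
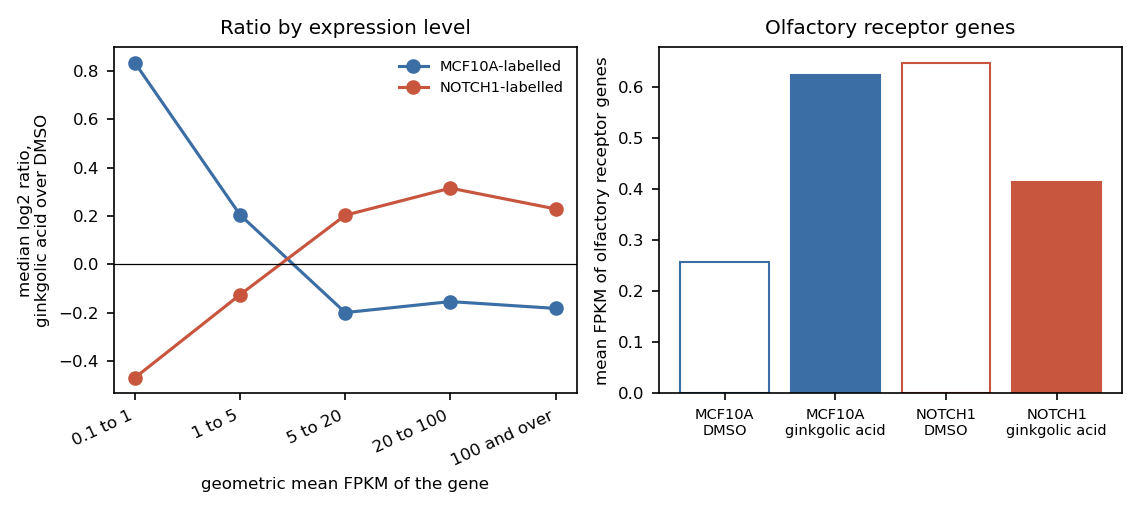
Median log2 ratio of ginkgolic acid over DMSO by geometric mean FPKM of the gene in both lines, and mean FPKM of olfactory receptor genes in the 4 groups. Genes between 0.1 and 1 FPKM lie at 0.83 in MCF10A and −0.47 in NOTCH1-labelled cells, and olfactory receptor genes at 0.624 and 0.258 FPKM in MCF10A and 0.413 and 0.646 in NOTCH1-labelled cells with ginkgolic acid and DMSO.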

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

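The tests on olfactory receptor genes had their predictions written before their result was seen, although the gene set was chosen after seeing the data, and the other tests in this part were chosen only after the result was seen. None of the differences between the lines given here was tested, since each group has 1 value per gene.

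Several gene lists stood out because their medians lay on opposite sides of 0 in the lines and their differences lay above the range of random lists. The median difference of the log2 ratios, NOTCH1-labelled minus MCF10A, was 2.74 for keratinocyte differentiation genes, 1.19 for basal markers, 1.17 for Notch targets and 1.07 for p53 targets. It was 0.97 for genes of S phase and DNA replication, 0.83 for nuclear genes of oxidative phosphorylation and 0.80 for glycolysis and hypoxia-responsive genes. Except for Notch targets, each of these lists had a median inside the range of random lists in at least 1 line.

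Single genes stood out because they differed at least 4-fold between ginkgolic acid and DMSO in both lines and in opposite directions. Of the 11781 genes with at least 1 FPKM in all 4 groups, 11 did so, beside 115 with the same direction. Higher in NOTCH1-labelled and lower in MCF10A cells were PAQR5 with a difference of 11.51, RALGAPA1 with 11.50, ANKRD54 with 11.48, UBAP2 with 9.45, AC005076.5 with 6.17, RP11-10G12.1 with 5.92 and KRT16 with 4.67. The other way were SLC9A3R1 with −7.64, AL591516.5 with −5.75, GPR98 with −4.70 and AC105036.1 with −4.64. Of the 7 of these genes with an annotation, 3 hold a small RNA, where 1.12 would by length (0 to 3 in random draws). AC005076.5, RP11-10G12.1, GPR98 and AC105036.1 lie outside the rule for named genes and were chosen after their values were seen.

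Unnamed loci, outside the genes used above, went different ways by length and line. There were 12725 unnamed loci longer than 51 bases at 1 FPKM or more with ginkgolic acid in MCF10A, against 5329 with DMSO. In NOTCH1-labelled cells these numbers were 2981 and 4330. Of unnamed loci of exactly 51 bases, 224 reached 1 FPKM with ginkgolic acid in NOTCH1-labelled cells, against 177 with DMSO, and 384 in MCF10A, against 1917. Counts above the DMSO level were thus seen for longer loci in MCF10A and for loci of 51 bases in NOTCH1-labelled cells, and below it for the other combinations. The levels of loci of 51 bases were lower with ginkgolic acid in both lines. Their median log2 ratio was −2.06 over 152 loci in MCF10A and −1.77 over 40 in NOTCH1-labelled cells.

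Genes of G2 phase and mitosis were higher with ginkgolic acid in both lines. Unequal scaling of the groups is argued against, since the list's median exceeded that of all genes by 1.95 in MCF10A and 3.75 in NOTCH1-labelled cells. A larger share of cycling cells of all phases is not settled in MCF10A. The S phase list there had a median of −0.14 inside the range of random lists, which argues against it. Replication-dependent histone genes go the other way, with a median of 0.43, 16 of 42 at least 2-fold higher and 2 at least 2-fold lower. Their percentile of 100 was 93.7 against random lists not matched on expression. In NOTCH1-labelled cells this explanation stays open, since the S phase list had a median of 1.14 and histone genes 2.18. Cells held in G2 or mitosis may account for the pattern in both lines, a hypothesis found and examined on the same values. The mitotic list exceeded the S phase list by 1.98 and 2.75. The 2 lists need not change equally with a larger share of cycling cells, so this excess cannot separate the 2 explanations. Culture density, which the labels do not give, was not tested.

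Keratinocyte differentiation genes were lower with ginkgolic acid in MCF10A and not in NOTCH1-labelled cells. That these genes were already low in NOTCH1-labelled cells is argued against by their DMSO values, with a median log2 ratio of −0.25 between the lines, across tables normalized separately. Noise near the detection limit is argued against as well, since the 12 members with at least 5 FPKM in both DMSO groups had a median difference of 2.74. An effect of NOTCH1 may account for the difference but was not tested, and the NOTCH1 values go against the label.

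Genes at low level were higher with ginkgolic acid in MCF10A and lower in NOTCH1-labelled cells. A lower depth of 1 group would leave the mean of olfactory receptor genes in place if each listed 0 is a true 0. On that condition the ratios of 2.42 and 0.639 argue against it. A listed 0 can be a failed estimate, however, and the group with the lower mean had more of them. In MCF10A 64 of these genes were at 0 with ginkgolic acid and 251 with DMSO, and in NOTCH1-labelled cells 185 and 79. Reads spread over the genome outside expressed genes, from DNA or unspliced RNA, could account for the pattern, and both ratios moved in its direction. Olfactory receptor genes are themselves at low level and were chosen after the pattern was seen. Their ratios thus largely restate the pattern and cannot decide on its cause. The counts of unnamed loci longer than 51 bases go the same way, and those of loci of exactly 51 bases go the other way in both lines. The levels of loci of 51 bases go the other way in MCF10A and the same way in NOTCH1-labelled cells. A biological origin was not tested.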

How the results depend on the processing

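The settings that keep joined or unnamed loci, centre lists on the median gene, add members on joined loci and leave out genes that hold small RNAs were chosen only after the results were seen. No paired analysis was possible because the columns carry 1 value per group and no replicate number. For the same reason leaving out a replicate, a stricter q-value, a recomputed adjustment, count models and a pseudocount of 0.1 on values per sample were not run. The depth is unknown, so its limits on these values cannot be stated. The cause of the shifts below was not tested unless the setting itself gives it.

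Counts of genes beyond 2-fold moved most with the treatment of low values. Without a minimum FPKM, 8280 genes were higher in MCF10A and 6755 lower in NOTCH1-labelled cells. With a minimum of 5 FPKM, fewer genes entered, and 1166 were higher and 1561 lower in MCF10A (42.8% higher), and 1941 and 929 in NOTCH1-labelled cells (67.6% higher). The same minimum gave 2174 and 700 genes with a larger and a smaller response in NOTCH1-labelled cells, 425 and 312 genes higher and lower in both lines, and an r of 0.38. A pseudocount of 1 FPKM gave 2113 and 1693 in MCF10A and 2272 and 1746 in NOTCH1-labelled cells. With unnamed loci kept, 7903 were higher and 4036 lower in MCF10A, and 5569 lower in NOTCH1-labelled cells.

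A list median counted as moved when it shifted by more than 0.5 of the width of its random 95% range, and percentiles were read against that range. The direction reversed with the mean for luminal markers (−0.45) and ribosomal proteins (−0.13) in NOTCH1-labelled cells. The mean was −0.11 for Notch targets in MCF10A, at a percentile of 28.8, and in NOTCH1-labelled cells 1.86 for ATF4 and CHOP targets, 1.03 for p53 targets and 1.21 for the unfolded protein response. With the mean, luminal markers of MCF10A moved outside the range at 1.01, and interferon-stimulated genes (10.3), mesenchymal markers (97.3) and luminal markers (4.47) of NOTCH1-labelled cells moved inside it. A pseudocount of 1 FPKM gave a median of 3.57 for the mitotic list, and percentiles of 2.56 for interferon-stimulated genes and 85.3 for luminal markers in NOTCH1-labelled cells. Random lists not matched on expression put the MCF10A lists of NRF2 at 89.6, cholesterol at 94.0, the unfolded protein response at 82.5 and histones at 93.7 inside the range, and in NOTCH1-labelled cells interferon-stimulated genes at 6.91 and ribosomal proteins at 54.2. With a minimum of 5 FPKM, the median of inflammatory genes in MCF10A was −0.57 and that of fibroblast markers in NOTCH1-labelled cells 0.65. The same minimum put Notch receptors of MCF10A (2.91) and ribosomal proteins of NOTCH1-labelled cells (3.4) inside the range, and mesenchymal markers of MCF10A (99.2), apoptosis regulators (1.41) and inflammatory genes (0.94) of NOTCH1-labelled cells outside it. Members on joined loci gave a median of 0.75 for histones in MCF10A and a percentile of 91.1 for luminal markers in NOTCH1-labelled cells. Without genes that hold small RNAs, Notch receptors (3.02), the unfolded protein response (92.5) and ribosomal proteins (3.52) in MCF10A, and ribosomal proteins (4.18) and TGF-beta and YAP targets (96.4) in NOTCH1-labelled cells, lay inside the range. Removing the median of genes with at least 1 FPKM in both groups flipped the sign of 7 of 70 list medians. Of the 40 highest and lowest ratios, 13 moved by more than 1.5-fold with a pseudocount of 1 FPKM and 0 reversed. The lists of G2 phase and mitosis and of ATF4 and CHOP targets lay above the range in both lines under every setting run. Keratinocyte differentiation genes also kept their direction and place, below the range in MCF10A and inside it in NOTCH1-labelled cells.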

Other observations

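The tests on short loci and on the order of the genes in this part were chosen only after the result was seen.

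Some of the gene lists not described above had medians outside the range of random lists in NOTCH1-labelled cells. There, DNA damage repair genes had a median log2 ratio of 0.96, with 15 of 31 at least 2-fold higher, and FANCI, of the Fanconi anemia pathway, had a log2 ratio of 2.73. The median in MCF10A was 0.17, inside the range. Heat shock genes had medians of 0.12 in MCF10A, at a percentile of 88.6 and so inside the range, and 0.99 in NOTCH1-labelled cells, where 10 of 21 were at least 2-fold higher, among them HSPA1B with a log2 ratio of 2.56. Metallothioneins had −0.45 and 1.28, and MT2A was at 1269 and 482 FPKM in MCF10A and at 2717 and 444 in NOTCH1-labelled cells. Immediate early and MAPK feedback genes had 0.50 and 0.82, and DUSP1, a MAPK phosphatase gene, was at 190.1 and 29.3 FPKM in MCF10A and 395 and 22.8 in NOTCH1-labelled cells. TGF-beta and YAP targets had 0.06 and 0.79. Mesenchymal markers had −0.01 and 0.85, and VIM, encoding vimentin, was at 106 and 24.8 FPKM and at 142 and 20.5.

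Most of the other lists lay inside the range of random lists in both lines, with autophagy and luminal markers in NOTCH1-labelled cells as the exceptions. Autophagy and lysosome genes had medians of −0.30 in MCF10A and 0.67 in NOTCH1-labelled cells, and nuclear genes of oxidative phosphorylation −0.33 and 0.45. Glycolysis and hypoxia-responsive genes had −0.20 and 0.35, although VEGFA was at 62.4 and 12.6 FPKM in MCF10A and 123 and 17.9 in NOTCH1-labelled cells. Fatty acid synthesis genes had −0.39 and 0.53, and GPAM, of triglyceride synthesis, was at 1.36 and 15.7 FPKM and at 2.45 and 15.4. Fatty acid oxidation genes had −0.07 and 0.36, aryl hydrocarbon receptor targets 0.49 and 0.27, apoptosis regulators −0.17 and −0.01, inflammatory and NF-kB targets −0.10 and −0.02, and luminal markers −0.11 and 0.70. The medians of fatty acid oxidation, inflammatory, mesenchymal and luminal lists in MCF10A flip sign when the median of genes with at least 1 FPKM in both groups is removed, and the luminal value in NOTCH1-labelled cells is −0.45 with the mean. Of mitochondrially encoded genes 2 were measured outside joined rows, MT-ND6 at 947 and 3898 FPKM in MCF10A and 1727 and 1650 in NOTCH1-labelled cells, and MT-CYB at 445 and 906 and at 486 and 614, and no list median was formed.

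Genes that were at least 4-fold higher in 2 groups than in both others, with at least 5 FPKM, numbered 112 for ginkgolic acid in both lines, 57 for DMSO in both, 54 for the NOTCH1-labelled groups and 26 for the MCF10A groups. The crossed pairings gave 67 for MCF10A with ginkgolic acid and NOTCH1-labelled cells with DMSO, and 20 for the reverse. Genes of the NOTCH1-labelled groups, chosen after their values were seen, included LCN2, an iron-siderophore binding protein, at 72.5 and 69.2 FPKM against 1.26 and 1.73. HLA-B, of antigen presentation, was at 192 and 140.1 FPKM against 23.0 and 13.2. These levels come from separately normalized tables.

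Each table runs through the chromosomes 2 times. In the first runs, no gene between 10 and 1000 FPKM had an absolute log2 ratio under 0.5, among 1100 genes in MCF10A and 1109 in NOTCH1-labelled cells, and the smallest was 0.52. In the second runs 2810 of 4083 and 2864 of 4518 such genes lay under 0.5. The first runs may hold the genes that the authors called different, a hypothesis that the value of 0.52 leaves standing. They held 1250 genes higher and 1704 lower in MCF10A, and 1529 higher and 668 lower in NOTCH1-labelled cells.

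Values of unnamed loci of 51 bases lie on a few steps, such as multiples of 11072 FPKM for 97.0% of 1917 loci in the MCF10A DMSO group. A step may be the worth of 1 read of 1 library. In MCF10A, the ratio of steps between groups at 51 bases, 0.946, recurred within 0.1% at 26 of 48 other lengths between 52 and 120 bases. It recurred at 42 of these when ratios of counts of 10, 11 and 12 were allowed, a wider test set after the first version was seen. In NOTCH1-labelled cells it recurred at 0 of 11 lengths, too few to decide.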
